A study of Drosophila melanogaster with 4 samples.

How the data were processed

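Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used on larvae of Drosophila melanogaster of the Oregon-R wild-type strain, collected at the last larval instar. Per the labels' protocols, tissue was homogenised and fixed with formaldehyde, chromatin was sheared by sonication, and fragments were recovered with an antibody on beads. Per the labels, the antibody targets histone H3 trimethylated at lysine 79 (H3K79me3). The labels list 4 samples, which are 2 ChIP libraries and 2 input libraries of unselected chromatin. Values from the input libraries were not analysed here, so no background measured in the same way could be set beside the ChIP values.

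The authors deposited region lists, 1 for each ChIP replicate and 1 for the whole series, whose name marks it as belonging to the replicate set. Regions were therefore called per replicate as well as in a combined list; how the replicates were combined is not given in the sources used here. Coordinates are on FlyBase release 5, per the file headers. Bowtie 0.12.7 is named in the submitters' processing notes. The region caller, its threshold, the sequencing depth and the way in which the input was used are not given in the sources used here. Each region carries a score that the authors deposited without a unit. It was used to describe, rank, filter or compare regions within 1 list, and differences between X and autosomes found within each replicate list were also averaged. The other deposited values are the first and last base of each region, 1-based per the file headers. Each list names its entries as regions of enrichment or of depletion. The depleted entries, 2 in replicate 1, 0 in replicate 2 and 7 in the series-wide list, were kept apart from all comparisons.

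Overlapping or touching regions were joined before base pairs were counted. Covered length was divided by the sequence lengths in the file headers. The 5 large arms are 2L, 2R, 3L, 3R and X, and the 6 main arms add chromosome 4. The heterochromatic sequences are the 6 scaffolds that this release keeps apart (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet). U holds unplaced sequence. Values over replicates are the mean ± SD with n = 2. The labels do not say whether the replicates came from separate collections of larvae, so the SD may be technical. The overlap of the replicate lists was measured as the base-pair Jaccard index, the shared length divided by the length covered by either list. It was compared with 1000 random circular shifts of replicate 2 within each of the 6 main arms (one-sided permutation test, whose smallest possible p is 0.001). A region was counted as shared when it overlapped the other list by at least 1 bp, and shares carry 95% Wilson intervals, which cover counting error only. For the X against the autosomal arms, the large arms were cut into 1 Mb blocks, and whole blocks were reassigned at random between X and autosomes (two-sided permutation tests, 100000 draws for covered length and for counts of wide regions, 10000 for scores). Intervals of these differences come from resampling blocks. Neighbouring blocks are not independent replicates, and these p-values describe variation along the genome, not between larvae. The X comparison had been planned as a description without a test, and its block tests, like every comparison of scores between arms, were added after the data were seen. Scores were compared between X and autosomes with and without matching on 10 width groups. The depth behind each value is unknown, because region lists hold no read counts, and no interval or detection floor that needs depth is given.

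Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap code was tested on 4 simulated lists, in which the Jaccard index equalled a base-by-base count in 4 of 4. The shift test called 3 of the 3 lists that had kept some of their regions. The block test called 5.75% of 400 simulated runs with no difference, and 99.25% of 400 runs with a difference of 1 SD between block means. Those runs drew independent, normally distributed block values. They do not cover dependence between neighbouring blocks, nor the test of scores, which compares medians over regions.

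The regions named in the text are the 10 with the highest score and the 5 widest in the series-wide list, by a rule written before the data were examined. Extreme blocks, region-free stretches and single regions outside that rule were chosen after their values were seen. The planned comparisons of genes (features covered, gene ends, lists of genes) were not made. They need a gene annotation of release 5, and the gene table at hand is on release 6; coordinates were not converted between releases, so no gene is named. Alternatives were the top 50% of each list by score, regions closer than 500 bp merged, other overlap rules (shares of regions, each set against 1000 shifts), the series-wide list in place of the replicates, and each replicate alone. Restricting the X comparison to bases within genes was not run for the same reason.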

Results

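The data set recorded where H3K79me3 was enriched in the genome of wild-type larvae at the last larval instar. Trimethylation of histone H3 at lysine 79 is deposited by the Dot1 methyltransferase, called grappa in flies, and is generally found over transcribed genes. Regions called by the authors were compared between 2 ChIP replicates and with the series-wide list. The comparisons ask how reproducible the map was, and how the mark was spread over chromosomes with different properties. Region lists carry no read counts, so the depth of each library is unknown.

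H3K79me3 covered a similar share of the main chromosome arms in both replicates. Replicate 1 held 5114 enriched regions and replicate 2 held 4689, a mean of 4902 ± 301 (SD, n = 2). They covered 29.5 Mb in replicate 1 and 28.5 Mb in replicate 2 (SD 0.669 Mb, n = 2). This was 24.4% of the 6 main arms in replicate 1 and 23.6% in replicate 2. The median region was 3606 bp wide in replicate 1 and 3790 bp in replicate 2, and the narrowest was 1301 bp in both. Regions of at least 20 kb numbered 180 in replicate 1 and 179 in replicate 2, and held 17.2% and 18.3% of the covered length. All of these wide regions lay on the 5 large arms, and every one overlapped a region of the other replicate. Wide regions also scored higher than the narrower ones, with a median score of 1.72 against 0.913 in replicate 1 and 1.58 against 0.853 in replicate 2. Across regions within a list, score and width rose together (Spearman's rho 0.797 in replicate 1 and 0.800 in replicate 2, where regions are not independent replicates).

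The same parts of the genome were called in both replicates. The lists shared 27.2 Mb of the main arms, which was 92.5% of the length covered in replicate 1 and 95.6% of that in replicate 2. The Jaccard index was 0.886, against a mean of 0.138 and a maximum of 0.213 over 1000 shifted placements (one-sided permutation p = 0.001, the smallest these shifts can give). It lay between 0.872 on the X and 0.892 on 3R among the large arms. Chromosome 4, the small dot chromosome with a largely heterochromatic character, was lower at 0.721. Of the replicate 1 regions, 89.5% (95% Wilson interval 88.7 to 90.3%) overlapped a region of replicate 2, and 95.3% (94.7 to 95.9%) of the replicate 2 regions overlapped one of replicate 1. On the main arms, shifted placements gave a mean of 36.1% for replicate 1 and 37.8% for replicate 2. Regions without a counterpart were mostly low-scoring. Each list was divided by score into 4 groups of about equal size. In the lowest group of replicate 1, 67.8% (65.2 to 70.3%) of regions had a counterpart, against 1279 of 1279 in the highest. Chance overlap also rose with score, since width did: the mean over shifts was 29.7% in the lowest group and 43.1% in the highest. In replicate 2, 84.5% (82.3 to 86.4%) of regions in the lowest group and 99.7% (99.3 to 99.9%) in the highest had a counterpart. The means over shifts for these groups were 30.9 and 45.2% on the main arms.

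**Figure D1:**
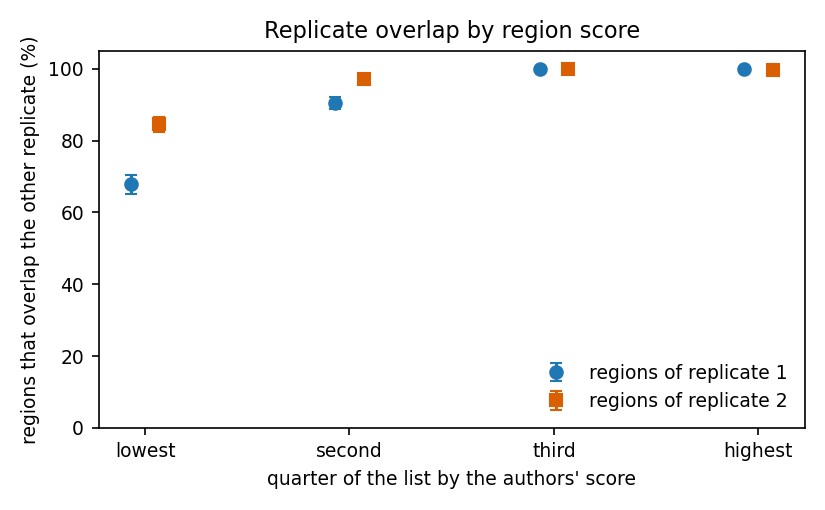
Share of the regions of each replicate (vertical axis, percent) that overlap a region of the other replicate by at least 1 bp, in 4 groups of each list by the authors' score (horizontal axis). Points are shares and bars are 95% Wilson intervals; the lowest group stands at 67.8% for replicate 1 and 84.5% for replicate 2, and the highest at 100% and 99.7%.

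The series-wide list was longer than either replicate list and contained nearly all of both. It held 5331 enriched regions over 32.6 Mb, and 99.6% of the length covered in replicate 1 and 99.8% of that in replicate 2 lay inside it. Of its covered length, 83.6% was also covered in both replicates, 10.2% in 1 replicate and 6.11% in neither. By regions, 3997 met both replicates, 473 met replicate 1 alone, 187 met replicate 2 alone and 674 met neither. The median score within this list was 0.358 for the regions that met neither replicate and 0.845 for those that met at least 1. The list also held 425 regions narrower than the narrowest replicate region of 1301 bp, and 370 of these met neither replicate. The replicate lists and the series-wide list come from the same libraries, so their overlap is not an independent check.

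The highest-scoring regions were spread over several chromosomes. Of the 10 highest scores in the series-wide list, 3 were on the X, 2 on 2R, 2 on 3L, 1 on 3R, 1 on U and 1 on 2RHet, and 8 had a region in both replicates. On 2R, the region from 1988368 to 2038702, 50.3 kb wide with a score of 2.48, was covered to 99.8% in replicate 1 and 99.9% in replicate 2. On the X, the region from 15212672 to 15220954 (score 2.47) ranked 10 by score in replicate 1 and 1 in replicate 2. The region on the X from 6634854 to 6639062 scored 2.40, and the one on 3R from 20048758 to 20074200 scored 2.39. On 3L, the region from 17545508 to 17551628 scored 2.41, and on 2R the one from 15998434 to 16004634 scored 2.40. An unplaced sequence held the region on U from 7541886 to 7544714, with a score of 2.38, which ranked 2 in replicate 1 and 26 in replicate 2. The other 2 had no region in either replicate. They were the highest score of all, 3.08 on the X from 2965030 to 2966030, and a score of 2.39 on 2RHet from 1427960 to 1428962. These were 1001 and 1003 bp wide, below the narrowest replicate region.

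The widest region lay on 3L from 17937562 to 18042520. It spanned 104959 bp with a score of 2.44, the fourth highest of the list, and was covered to 98.4% in replicate 1 and 99.0% in replicate 2. Replicate 2 called it as a single region of 103875 bp, while replicate 1 called 2 regions, the wider of 96079 bp. The next widest were on 3R from 9794858 to 9862084 (67.2 kb) and from 10554458 to 10617186 (62.7 kb). They were followed on 3L by 8819800 to 8880754 (61.0 kb) and 516754 to 574800 (58.0 kb). Each was covered to more than 95% in both replicates, but in up to 4 pieces, and by score they ranked 1081, 957, 877 and 177 in the series-wide list. Genes in these regions were not analysed here.

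**Figure D2:**
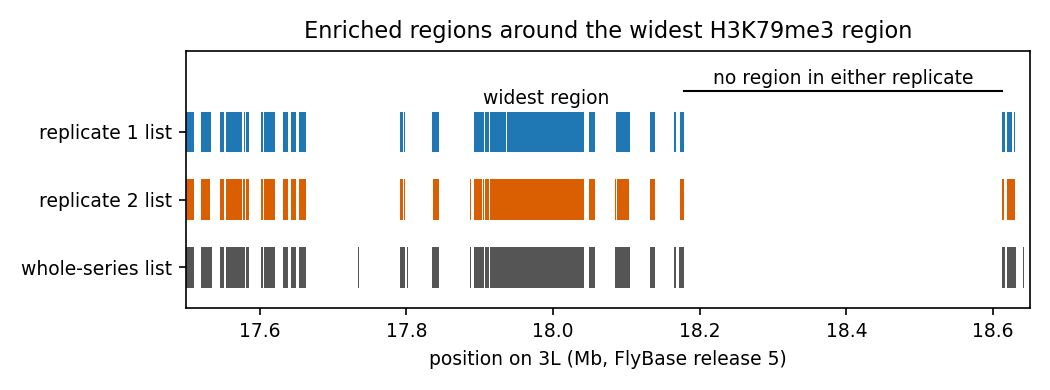
Enriched regions (filled blocks, to scale) of the 3 lists along part of arm 3L, with position in Mb on FlyBase release 5 on the horizontal axis and 1 row per list. The widest region of the series-wide list, 104959 bp from 17937562 to 18042520, appears in all lists, and the black line marks a 433 kb stretch with no region in either replicate.

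The mark was distributed unevenly between euchromatic arms, chromosome 4 and heterochromatic sequence. Of the large arms, 2R had the highest covered share, 26.9 ± 0.695% (mean ± SD, n = 2 here and in the next 3 sentences), and 2L the lowest, 22.0 ± 0.455%. The values were 23.9 ± 0.337% for 3L and 25.03 ± 0.753% for 3R. Chromosome 4 was covered to 8.15 ± 1.62%. The 6 heterochromatic sequences together were covered to 0.509 ± 0.0795%. The order of the large arms was the same in both replicates. Chromosome 4 lay below each large arm and above heterochromatic sequence in both. With 2 replicates no test across libraries was made. How much of chromosome 4 and of the heterochromatic scaffolds could be mapped uniquely is not known from region lists, and lower mappability would lower these shares.

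Heterochromatic sequence nevertheless held some reproducible regions. Replicate 1 listed 19 regions there and replicate 2 listed 24, and 18 overlapped between them. The single region on YHet, a scaffold of Y-chromosome heterochromatin, ran from 304601 to 307719 in replicate 1 and from 304695 to 307708 in replicate 2, with scores of 1.57 and 1.52. Those scores, the highest of the heterochromatic regions in each replicate, lay above the upper quartile of each list (1.45 and 1.31). On 2RHet, a region from 469829 to 472473 in replicate 1 scored 0.946 and its counterpart in replicate 2 scored 1.12. Most heterochromatic regions were low-scoring: 3 of 19 in replicate 1 and 4 of 24 in replicate 2 scored above the median of their list.

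**Figure D3:**
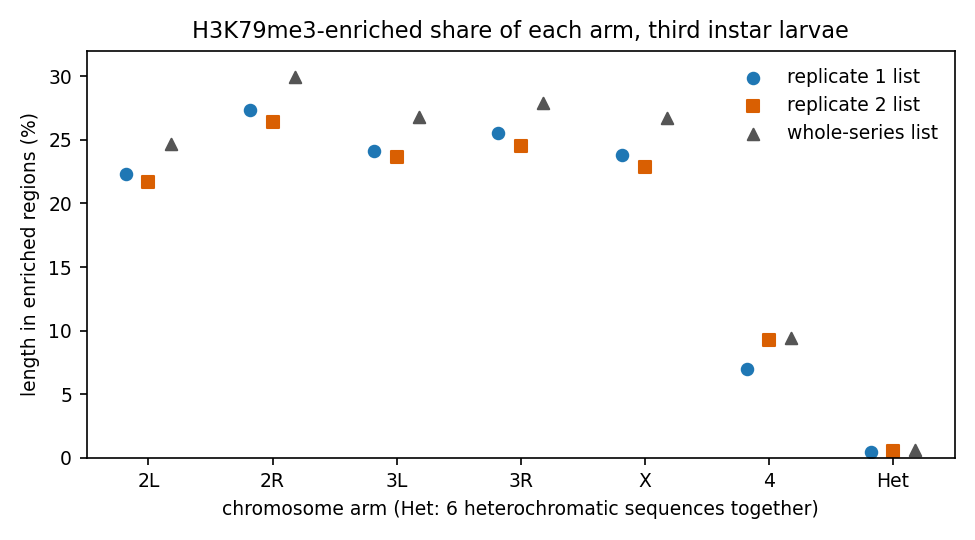
Length inside enriched regions as a percentage of each arm (vertical axis) for the 5 large arms, chromosome 4 and the 6 heterochromatic sequences together (Het, horizontal axis). Each point is 1 list; the large arms stand between 21.7 and 27.4% in the replicates, chromosome 4 at 7.00 and 9.30%, and Het at 0.453 and 0.566%.

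On the X, which carries the MSL dosage compensation complex in males, the covered share was not detectably different from that of the autosomal arms, given the variation along chromosomes. It was 23.3 ± 0.690% (SD, n = 2), and the ratio to the mean of 2L, 2R, 3L and 3R was 0.955 ± 0.00634 (SD, n = 2). Over 1 Mb blocks, X minus autosomes was -0.718 percentage points in replicate 1 (22 X and 95 autosomal blocks, 95% interval -4.47 to 3.07, two-sided permutation p = 0.729) and -0.920 in replicate 2 (-4.53 to 2.71, permutation p = 0.641). Wide regions of at least 20 kb numbered 27 on the X in each replicate. That was 1.23 per block, against 1.59 per block on the autosomal arms in replicate 1 and 1.58 in replicate 2 (permutation p = 0.289 and 0.272). The direction of the ratio depended on the measure: counted as regions per Mb, it was 1.02.

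Scores of regions on the X were higher than those on the autosomes within each replicate list, in a comparison added after the data were seen. The median was 1.05 on the X and 0.918 on the autosomal arms in replicate 1, a difference of 0.137 (95% interval 0.0617 to 0.193, block permutation p = 0.0004). In replicate 2 it was 0.978 against 0.864, a difference of 0.114 (0.0476 to 0.176, block permutation p = 0.0008). After matching on width the difference was smaller, 0.0785 in replicate 1 and 0.0701 in replicate 2. The X had the highest median of the 5 large arms in both replicates. Within the top 50% of each replicate list by score the sign was reversed and no difference was detectable, at -0.00381 in replicate 1 and -0.00142 in replicate 2 (block permutation p = 0.898 and 0.971). In the series-wide list it was 0.00386 (block permutation p = 0.916), without a reversal. That subset is defined by the score compared. In the top 50% of replicate 1 by score lay 544 of the 969 X regions and 1986 of the 4079 autosomal ones. Of the top 10% of large-arm regions, 23.4% (95% Wilson interval 19.9 to 27.3%) lay on the X in replicate 1 and 22.6% (19.0 to 26.6%) in replicate 2, against 19.2% of all large-arm regions in each; the interval of replicate 2 includes that share. The scale of the score is not given in the sources used here.

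Along the large arms, the replicates followed each other closely. In 117 blocks of 1 Mb, the covered share differed between replicates by a median of 0.812 percentage points and by at most 3.09. The difference was mostly in 1 direction, with 102 of the 117 blocks lower in replicate 2. The mean of the replicates ranged from 1.02 to 48.5% between blocks. By the mean of the replicates, the densest block was on 3R from 5000001 to 6000000, with 49.3% covered in replicate 1 and 47.6% in replicate 2. It was followed by 3L from 8000001 to 9000000 (41.5 and 40.9%) and X from 1000001 to 2000000 (42.4 and 39.3%). The sparsest blocks were at centromere-proximal ends. They were 3L from 23000001 to 24000000 (0.740 and 1.30%), 2R from 1 to 1000000 (2.06 and 2.92%) and 2L from 22000001 to 23000000 (3.98 and 4.20%). Each of these was higher in replicate 2, and relative to its low share the difference on 3L was large.

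**Figure D4:**
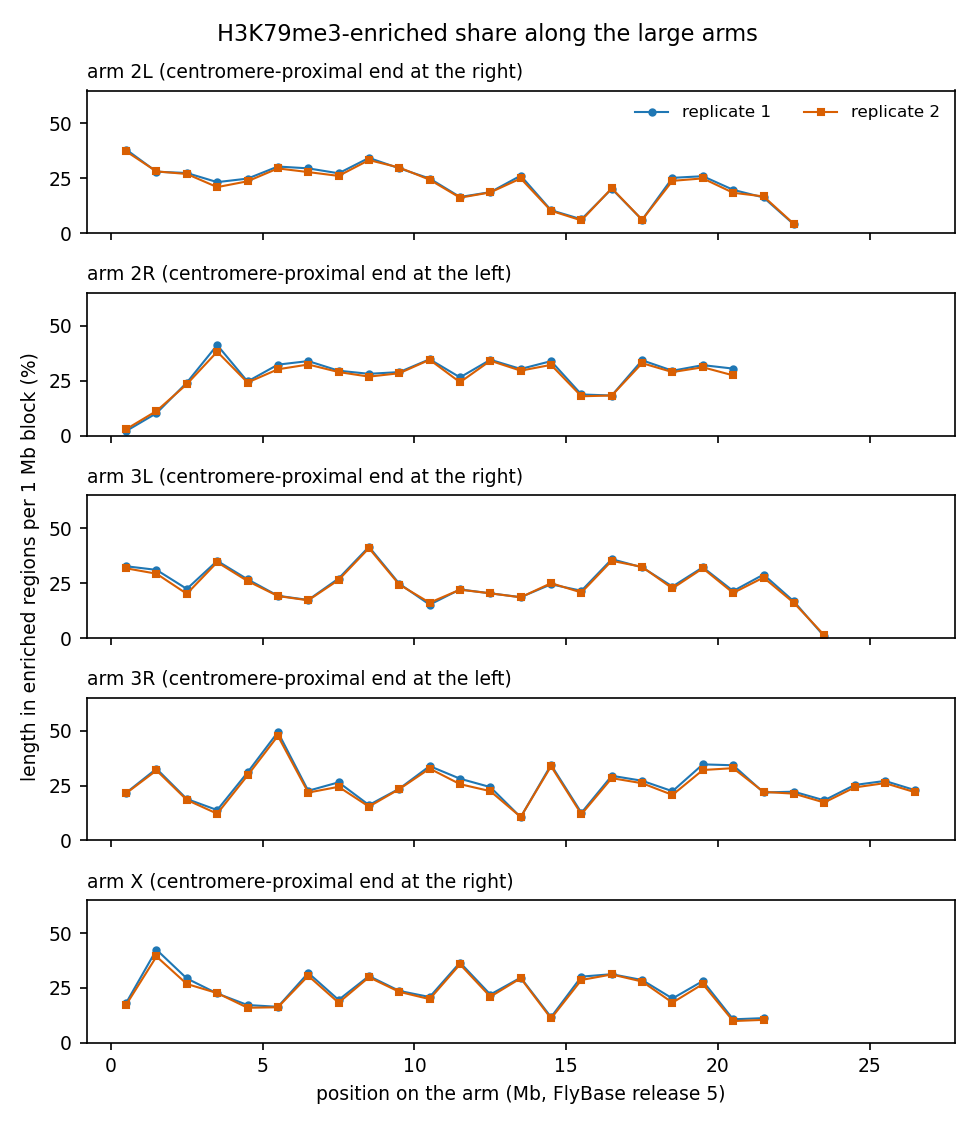
Share of each 1 Mb block inside enriched regions (vertical axis, percent) against position on the arm in Mb (horizontal axis), for the 5 large arms and both replicates. Each point is 1 block in 1 replicate. The replicates differ by at most 3.09 percentage points in any block, and the mean of the replicates ranges from 1.02 to 48.5% between blocks.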

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

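The test of calling everywhere on chromosome 4 and the test of the 304 wider series-wide regions were chosen after their results were seen, and the others here were written after the lists had been looked at but before their own results.

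Signal lay in sequence that no comparison between arms used. The unplaced sequence U held 11 regions in replicate 1, 11 in replicate 2 and 20 in the series-wide list, and 8 of the 11 in each replicate overlapped the other. Their median score was 1.32 in replicate 1, above the 0.946 of the whole list, and 0.836 in replicate 2, below the 0.881 of the whole list. The series-wide list also names 7 depleted regions, between 1581 and 1755 bp wide, each with a negative score. Of these, 3 overlap an enriched region of replicate 1, 3 an enriched region of replicate 2, 1 a depleted region of replicate 1 and 1 no region of either, with 1 counted for both replicates. On 2R from 10532358 to 10534112 both replicates called enrichment, with scores of 0.0447 and 0.105, where the series-wide list gives depletion with a score of -0.00182. The replicates also disagreed on 3LHet from 600057 to 601698. Replicate 1 names it depleted (score -0.0625), while replicate 2 (0.257) and the series-wide list (0.0684) give enrichment there. No region called enriched has a negative score in any of the 3 lists, so the sign of the score separates the names.

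Chromosome 4 was covered more in replicate 2 than in replicate 1, against the direction of every large arm taken as a whole. It held 36 regions over 94.7 kb in replicate 1 and 41 regions over 126 kb in replicate 2, a ratio of 1.33 (95% interval 1.20 to 1.59 from resampling 14 stretches of 100 kb). This interval and the next describe variation along chromosome 4, not between libraries. The rise was not particular to chromosome 4. The ratio was 1.25 for the heterochromatic sequences together, on 19 and 24 regions, and 1.07 for U. On 2RHet (1.63) and 3RHet (1.66) it was above that of chromosome 4. It was 1.14 on 2LHet and 1.30 on 3LHet, but below 1 on XHet (0.659) and YHet (0.966). The ratio was at most 0.980 on the 5 large arms, so covered length did not rise everywhere in replicate 2. This restates the observed pattern, so its outcome was fixed in advance and it gives no separate support. The ratio in the top 50% of each list was 1.38 (1.13 to 1.75), with 17 and 19 regions, which goes against extra low-scoring regions alone. The cut is the median of each list (0.946 and 0.881), so it differs between the lists, and few regions pass it. On chromosome 4, 9 replicate 2 regions had no replicate 1 region and 1 replicate 1 region had no replicate 2 region. In the whole lists these counts were 219 and 535. Local variation between lists stays open: none of 11 like stretches of the large arms reached 1.33 (0%, highest 1.05), but 11 are too few to exclude it. Those stretches were picked for a covered share near that of chromosome 4, which leaves out sparser sequence. The covered share of the proximal 2 Mb also rose in replicate 2 on 2L (9.80 to 10.2%), 2R (6.13 to 7.06%) and 3L (2.77 to 3.41%). It fell on 3R (27.2 to 26.7%) and X (8.02 to 7.64%). No biological explanation was tested.

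Of the regions in the series-wide list, 674 met no region of either replicate. A shorter minimum width in that list is a candidate explanation for part of them, since 54.9% were narrower than 1301 bp, the narrowest region of both replicates. It stays open for the other 304, which were at least that wide in the series-wide list but whose width in a replicate is not known. Of series-wide regions at least that wide that met a single replicate 1 region, 86.9% were wider than it. Weaker enrichment is in line with their scores, whose median was 0.358 against 0.845 for the rest, although score and width rise together. The 2 narrow regions on the X and 2RHet with scores of 3.08 and 2.39 go against weak enrichment for those regions. They are among 8 of the 370 narrow regions without a counterpart that scored above the median of the list.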

How the results depend on the processing

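Trimming replicate 1 to the number of regions in replicate 2, the width limit, the proximal 2 Mb and all score comparisons between X and autosomes were added after the data were seen. The Jaccard index of the replicate lists lay between 0.870 and 0.888 under its 4 alternatives, above each shift or shuffle (permutation p = 0.001). The shares of replicate 1 regions on the main arms shared by 1 bp, by 50% and by 50% reciprocally were 89.6, 87.6 and 79.5%, above each of 1000 shifts (permutation p = 0.001). The region count moved to 2451 and the covered length to 22.1 Mb when only the top 50% of each list by score was kept, which by construction removes regions. Under the same restriction, the share of the series-wide length covered by both replicates moved from 83.6 to 80.3%, the X to autosome ratio of covered share to 0.996, the share of chromosome 4 to 4.90% and that of the heterochromatic sequences to 0.104%. The difference in score between X and autosomes turned from 0.125 to -0.00262 on average over the replicates under that restriction, where the list is truncated by the very score compared, so this says little about the X. Leaving out series-wide regions narrower than 1301 bp gave a shared length of 84.9%. The X ratio was 1.02 by regions per Mb, 0.977 in the series-wide list and 0.968 without the proximal 2 Mb of each arm. Its direction was therefore not kept by region counts. More regions per Mb with a lower covered share means that regions on the X were narrower on average. Regions of at least 20 kb numbered 1.20 per Mb on the X, against 1.58 and 1.57 on the autosomal arms. Why this was so was not tested. The series-wide list put the heterochromatic share at 0.622%, and the cause was not tested. Merging regions closer than 500 bp gave 4164 regions and 29.2 Mb. With 2 replicates, leaving out either gives the single values in the report. Bases within genes and the alternatives of the gene results were not run, for lack of a release 5 annotation. No paired analysis was possible because the input libraries, which share replicate numbers with the ChIP libraries, gave no values here. Unknown depth and mappability limit what the absence of a region shows.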

Other observations

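The score tests on the X, the proximal test and the shuffle test were all added after the lists had been looked at, the first because higher X scores had been noticed. Large parts of the arms held no H3K79me3 region in either replicate. Stretches of at least 100 kb without a region numbered 207 on the 5 large arms and summed to 34.6 Mb, 29.1% of their length, with a median of 146 kb. The share was highest on the X (33.7%) and 2L (32.2%) and lowest on 2R (22.2%). The longest was on 3L from 24022874 to 24530228 (507 kb), followed by 2L from 16910934 to 17373486 (463 kb) and 3L from 18179137 to 18612091 (433 kb). The last of these lies on the same arm as the widest region of the series-wide list and begins after its end. On the X the longest ran from 20532618 to 20900863 (368 kb), and on 3R from 23812153 to 24146468 (334 kb). The series-wide list placed 54 regions inside 40 of these stretches.

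The hypothesis that regions gather along the arms was tested by shuffling the joined regions of both replicates within each arm. The observed 207 stretches compare with a median of 22 and a maximum of 36 in 1000 shuffles (one-sided permutation p = 0.001, the smallest these shuffles can give), in line with clustering. The shuffle treats all sequence as mappable, and repeats or assembly gaps may add to the count. It also places each joined region separately. Enriched sequence that was called as several close regions is thereby scattered, which may lower the count in shuffles.

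A second hypothesis was that centromere-proximal ends hold less of the mark. The proximal 2 Mb of the 5 large arms was covered to 10.8% in replicate 1 and 10.99% in replicate 2, against 25.9 and 24.97% of the rest (two-sided shift test, permutation p = 0.002 in each, the smallest these shifts can give). The proximal share was lower in 4 of 5 arms. On 3L the proximal end was covered to 2.77% in replicate 1 and 3.41% in replicate 2, against 25.4% of the rest of that arm in replicate 2. Arm 3R went the other way, with 27.2 and 26.7% proximally against 25.4 and 24.3% of the rest. Less transcription, lower mappability and the point at which release 5 ends each arm cannot be separated with region lists, which hold no reads.

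The higher scores on the X persisted after width was matched, but not within the top 50% of each replicate list by score, a subset defined by the score compared (-0.00262 on average, block permutation p = 0.898 and 0.971). Within width groups the difference was 0.0785 (95% interval 0.0602 to 0.0983) in replicate 1 and 0.0701 (0.0512 to 0.0896) in replicate 2, with a block permutation p of 0.0001 in both, the smallest these draws can give. Wider regions on the X are therefore argued against as the whole cause, as far as 10 width groups can show. The median width was 3713 and 3861 bp on the X, below 3L (3730 and 3962.5 bp) and 3R (3775 and 3944 bp). It was above that of 2L and 2R in both replicates. The score difference was 0.137 and 0.114 before matching. The X held 23.4 and 22.6% of the top 10% of large-arm regions by score, against 19.2% of all. An ordinary difference between single arms stays open, because 5 arms cannot give a share under 0.2; the X stood above the next arm by at least 0.101 in both replicates. A different balance of X and autosomal reads between ChIP and input could also move scores, and cannot be examined without the input values. Sex and dosage compensation were not tested, since the labels name no groups by sex.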
